A study of Mus musculus with 6 samples.

How the data were processed

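Messenger RNA levels were measured on 6 Affymetrix mouse expression arrays, 3 hybridised with RNA of miR-223 null neutrophils and 3 with RNA of wild-type neutrophils. The neutrophils were grown from bone marrow progenitors. Per the labels' protocols, the progenitors were kept for 6 days in an isotope-labelling (SILAC) medium with granulocyte colony-stimulating factor (G-CSF) and stem cell factor (SCF), then for 42 hours without SCF, and live cells were selected with magnetic beads. Total RNA was labelled with biotin by the manufacturer's standard protocol, per the labels. Groups and replicate numbers were taken from the sample titles. Nothing in the labels says whether replicates came from separate mice or cultures, so every p-value measures only the spread between these samples, which may be technical.

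The deposited table holds log2 intensity values for 45101 probe sets on 6 arrays. GCOS is named in the submitters' processing notes. The background correction, normalization and summary of probes were not given in the sources used here. That the values are base-2 logarithms was read from their range, with each array's highest value near 15.0, and from array medians that lay within 0.015 of each other. The values had therefore already been brought to one scale and were used as deposited. A normalization that forces arrays to one distribution removes any change in total mRNA and tends to balance rises and falls, so differences are relative to the other probe sets of the same array.

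The table names its rows only by probe set identifier. The reference table of 49997 mouse genes does not hold array identifiers, so probe sets could not be given gene names here. Exceptions are 64 manufacturer's control probe sets whose identifiers contain the name of the transcript. The tests fixed for 21 gene lists, for 1 value per gene and for miR-223 seed sites in 3' untranslated regions were therefore not run, and the level of miR-223 itself, which would check the labels, was not analysed here. The rule for named genes was fixed as the 12 largest rises and 12 largest falls past the threshold with no overlap between groups, together with genes of the lists, microRNA targets and the 3'/5' ratios of actin and Gapdh. Only the 2 largest rises and 2 largest falls are given, by identifier, along with the ratios. The control probe sets for the transferrin receptor were chosen after their values were seen.

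The 64 control probe sets were set aside. Of the remaining 45037, those whose mean over all 6 arrays was at or above the 40th percentile were kept, which left 27022 with a mean of at least 4.08. The difference null minus wild type was tested with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend in the variance), two-sided, at a Benjamini-Hochberg adjusted p under 0.05. No pseudocount was used because the values are logarithms. The fit without covariates was chosen as the main one before the data were examined, with the replicate number as a block as its alternative. Control probe sets were tested in a further pair of fits that kept them.

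Whether replicate numbers pair the arrays was decided before calls were compared. Deviations from the group mean, across the 27022 probe sets, correlated at r = 0.70 between null 1 and wild-type 1, at 0.30 between null 2 and wild-type 2 and at 0.48 between null 3 and wild-type 3. All 3 pairs exceeded 0.1, so the numbers were taken to pair the arrays and the blocked value is given wherever it changes a call. The mismatched pairs also passed 0.1: null 3 with wild-type 2 reached 0.41 and null 2 with wild-type 3 reached 0.21. With replicate 1 apart in both genotypes, deviations from a mean of 3 arrays make the remaining arrays correlate whatever their pairing. The rule therefore sets replicate 1 apart but cannot test the pairing of replicates 2 and 3. A block with replicates 2 and 3 swapped was not run. The labels do not say what the shared number stands for. The pairing comes from the data.

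The fitting code was tested on simulated data with the real means, pair effects and residual spreads of the 27022 probe sets and a set of changed probe sets, 50 per size. For this comparison without the block it recovered 60% of changes of 1 log2 unit and 90% of changes of 2 log2 units, and none of 50 changes of 0.5 log2 units. With the block it recovered 20% of changes of 0.5, 74% of changes of 1 and 80% of changes of 2 log2 units. At 1.5 log2 units recovery was 88% without and 94% with the block. Neither fit made a false call in these simulated data, where the pairing was true by construction and noise was drawn independently per probe set. The simulation gives no false-call rate for the real arrays or for a wrong pairing. Its recovery rates hold for 50 changed probe sets per size, while the blocked fit of the real arrays called 2703 in all. Values of single array features over 3 arrays per group were also compared with an exact two-sided permutation test, whose smallest possible p is 0.1. The precision is limited by the number of arrays. Alternatives were another filter or none, quantile normalization, median centring, a variance model without intensity trend, a stricter threshold, the block, and leaving out each array. Scan dates and detection calls were not used here.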

Results

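Neutrophils lacking miR-223, a microRNA abundant in the granulocyte lineage, were compared with wild-type neutrophils by mRNA profiling on arrays, 3 arrays per genotype. MicroRNAs repress mRNAs that pair with them, so the comparison asks how mRNA levels differ once this one is absent. The cells matured in culture from bone marrow progenitors. The 6 arrays gave closely matched distributions, with medians from 4.71 to 4.73 on the log2 intensity scale. Probe sets for bacterial tryptophan sequences, for which no transcript is expected, averaged between 2.77 and 2.86 on each array.

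The replicate 1 arrays of both genotypes stood apart from the rest, and the other 4 arrays grouped by genotype. The first principal component held 48.7% of the variance and set both replicate 1 arrays apart from the other 4. The second held 27.5% and separated the 3 null arrays from the 3 wild-type arrays. The correlation of null 1 with wild-type 1 across the 27022 kept probe sets was r = 0.994, above its correlation with null 2 (r = 0.990) and null 3 (r = 0.986). Null 2 was closest to null 3 (r = 0.995, against 0.993 with wild-type 2), and wild-type 2 to wild-type 3 (r = 0.997). Probe sets are not independent replicates, and these correlations describe the arrays only.

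**Figure D1:**
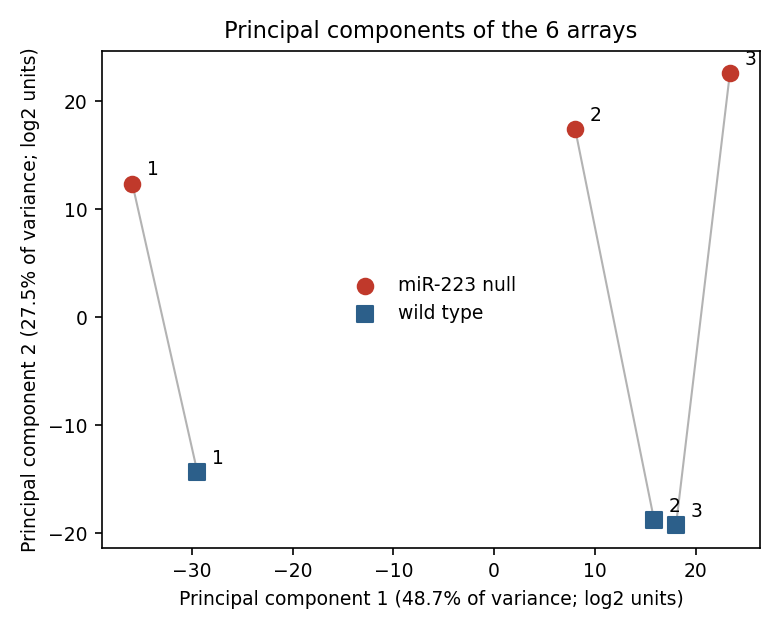
Principal components 1 and 2 of the 6 arrays (log2 units, 27022 probe sets), with circles for miR-223 null, squares for wild type, digits for the replicate number and grey lines joining arrays of one number. Component 1 sets both replicate 1 arrays apart, and component 2 separates the genotypes.

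RNA integrity was compared through the 3' and 5' probe sets of the named control transcripts, and neither an unpaired nor a paired exact test can pass 0.05 with 3 arrays each. The log2 difference between the 3' and 5' probe sets of beta-actin, a cytoskeletal protein, was 0.221 ± 0.050 (SD, n = 3) in null and 0.197 ± 0.053 (SD, n = 3) in wild-type arrays (exact two-sided permutation p = 0.6). For Gapdh, a glycolytic enzyme, it was -0.017 ± 0.091 (SD, n = 3) and -0.071 ± 0.016 (SD, n = 3), with an exact two-sided permutation p of 0.4. Both transcripts read within 1 log2 unit of the array maximum, which can compress such ratios. Among dimmer transcripts, the null minus wild-type change of the 5' minus 3' difference was -0.18 log2 units for pyruvate carboxylase, -0.14 for the transferrin receptor and 0.18 for 18S ribosomal RNA (exact two-sided permutation p = 0.3, 0.4 and 0.8). Within pairs, the 5' minus 3' difference was lower in null arrays in 3 of 3 pairs for actin, with changes of -0.022 to -0.030 log2 units, and for the transferrin receptor, with changes of -0.06 to -0.20. It was lower in 2 of 3 pairs for Gapdh, pyruvate carboxylase and 18S RNA. For 18S RNA it changed by 0.60 in the replicate 1 pair, against -0.03 and -0.02 in the pairs of replicates 2 and 3. The exact two-sided paired permutation p was 0.25 for actin and the transferrin receptor, the smallest that 3 pairs can give, and the unpaired test cannot go below 0.1.

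Loss of miR-223 was accompanied by changes at a small set of probe sets when the arrays were treated as unpaired, and most of these were higher in the null cells. Of 27022 probe sets, 51 passed an adjusted p of 0.05 (limma, Benjamini-Hochberg), 38 of them higher and 13 lower in null arrays. The count was 0 without null 2 or without wild-type 2 (2064 and 1753 at an unadjusted limma p under 0.05), 1 without wild-type 3, 3 without null 3, 34 without wild-type 1 and 58 without null 1. Of the 51, 29 differed by at least 2-fold, 21 higher and 8 lower. In all 51, the 3 null arrays lay entirely above or below the 3 wild-type arrays. Among all kept probe sets, 16.8% had no overlap between the genotypes, where the average over the 10 ways to split the arrays is 10%. As probe sets are not independent, any 1 split can depart from this average without a genotype effect. The median standard error was 0.125 log2 units, and the median size of a called change was 1.10 log2 units.

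Among the 51 unpaired calls, the 2 largest rises were probe sets 1455871_S_AT and 1424169_AT. Probe set 1455871_S_AT averaged 11.67 ± 0.12 (SD, n = 3) in null and 10.04 ± 0.29 (SD, n = 3) in wild-type arrays, a 3.10-fold rise (log2 difference 1.63, SE 0.15, limma adjusted p = 0.0135). Probe set 1424169_AT averaged 10.24 ± 0.09 (SD, n = 3) and 8.68 ± 0.18 (SD, n = 3), a 2.95-fold rise (log2 difference 1.56, SE 0.12, limma adjusted p = 0.0111). The 2 largest falls among the same 51 were 1419681_A_AT and 1437992_X_AT. Probe set 1419681_A_AT averaged 5.56 ± 0.26 (SD, n = 3) in null and 7.29 ± 0.13 (SD, n = 3) in wild-type arrays, and fell by 1.73 on the log2 scale (SE 0.15, limma adjusted p = 0.0123). Probe set 1437992_X_AT averaged 4.47 ± 0.27 (SD, n = 3) and 6.13 ± 0.05 (SD, n = 3), and fell by 1.66 on the log2 scale (SE 0.14, limma adjusted p = 0.0123). All 4 also passed with the replicate number as a block, where their limma adjusted p lay between 0.000163 and 0.0015. Without the block, all 4 calls were lost when null 2, wild-type 2 or wild-type 3 was left out, and 3 of the 4 when null 3 was left out. In these fits the differences stayed large. They were 1.52 to 1.67 log2 units for 1455871_S_AT, 1.48 to 1.59 for 1424169_AT, -1.69 to -1.87 for 1419681_A_AT and -1.51 to -1.73 for 1437992_X_AT.

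With arrays paired by replicate number, many more probe sets passed and rises and falls were nearly equal in number. The block raised the count from 51 to 2703, of which 1339 were higher and 1364 lower in null arrays, and all 51 probe sets of the unpaired fit were among them. Each of the 2703 moved one way in 3 of 3 pairs. Of all kept probe sets, 46.6% did so, where the average over the 4 ways to turn the pairs is 25%. This share too can depart from its average without a genotype effect, as probe sets are not independent. Most of these changes were small, with a median size of 0.37 log2 units. They ranged from -1.86 to 2.79 log2 units, beyond the unpaired calls at both ends. Rises formed 45.9% of the 2014 calls under 0.5 log2 units, 60.3% of the 614 calls between 0.5 and 1, and 60% of the 75 calls of 1 log2 unit or more. After quantile normalization 1354 blocked calls rose and 1208 fell, and rises formed 49.1% of the 1875 calls under 0.5. After median centring that share was 46.2% of 1871 calls. The excess of falls among small changes thus stayed after median centring and was smaller after quantile normalization. The count rests on how the variance was modelled: without the intensity trend, the blocked fit called 191 probe sets, 140 higher and 51 lower, all of them among the 2703. Without the replicate 2 pair it called 606, 385 higher and 221 lower. At an adjusted p under 0.01 it called 625, 403 higher and 222 lower. A block that set replicate 1 against the other replicates, tried after seeing the data, called 2417, of which 2329 were among the 2703.

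**Figure D2:**
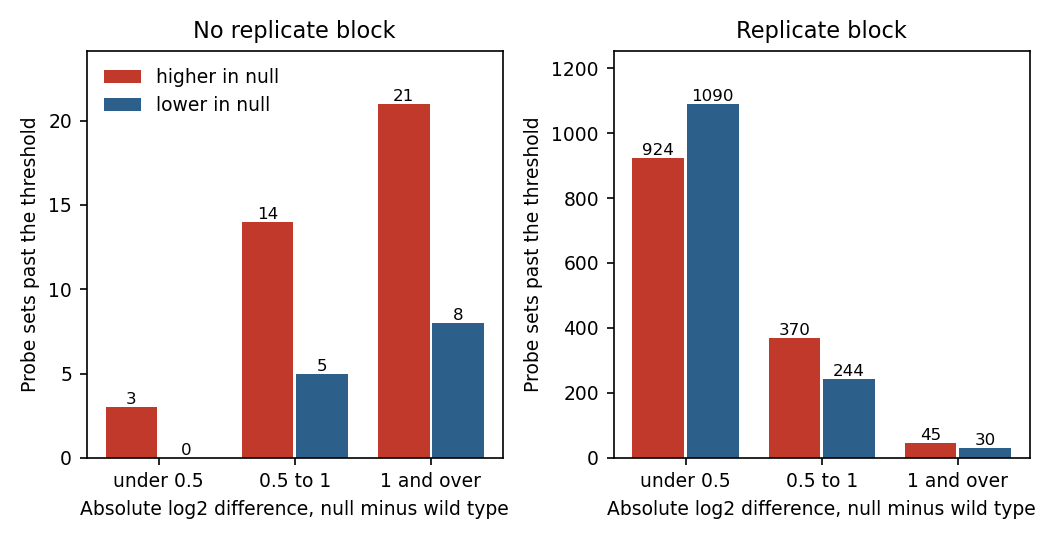
Number of probe sets past an adjusted p of 0.05 by size of the log2 difference between null and wild type, without (left) and with (right) the replicate block, on different vertical axes. In the values as deposited, rises outnumber falls in each size class except below 0.5 log2 units with the block, where 924 rose and 1090 fell.

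The share of calls differed with signal. With the block, 19.1% of the 9007 brightest kept probe sets passed, against 8.86% of the 9007 of middle signal and 2.03% of the 9008 dimmest. Called changes were smaller where the signal was higher, with a median size of 0.30 log2 units among the brightest and 0.57 among the dimmest. Of the 32 unblocked calls among the brightest probe sets, 29 rose and 3 fell. Among those of middle signal 4 rose and 4 fell, and among the dimmest 5 rose and 6 fell. With the block this excess among the brightest was absent, as 841 rose and 881 fell. Blocked calls of middle signal held 420 rises and 378 falls, and the dimmest 78 and 105.

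The transferrin receptor, which brings iron into the cell, was lower in null neutrophils in every pair. Averaged over its 3 control probe sets, its level was 7.35 ± 0.45 (SD, n = 3) in null and 7.90 ± 0.20 (SD, n = 3) in wild-type arrays, so the signal in null arrays was 68.1% of that in wild-type arrays. Null 3 held the lowest level, and without it the differences of the 3', middle and 5' probe sets were -0.27, -0.29 and -0.33 log2 units. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 can give. Within the pairs of replicates 1, 2 and 3 the difference was -0.30, -0.52 and -0.85 log2 units. Over all 6 arrays these probe sets differed by -0.48, -0.57 and -0.62 log2 units. None passed in the unpaired fit (limma adjusted p = 0.428, 0.456 and 0.472), and each passed with the block (limma adjusted p = 0.0307, 0.0323 and 0.0135). None passed with the block once the replicate 2 pair was left out (limma adjusted p = 0.107, 0.102 and 0.0723) or once the intensity trend was dropped (limma adjusted p = 0.112, 0.103 and 0.0702). The differences changed little: they were -0.50, -0.61 and -0.61 log2 units without the replicate 2 pair and unchanged without the trend.

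The other named control transcripts showed no difference that passed in either fit. The 3' probe set of beta-actin differed by -0.01 log2 units and that of Gapdh by -0.02. The 3' probe set for pyruvate carboxylase, which supplies oxaloacetate from pyruvate, differed by 0.05 log2 units (SE 0.11, limma adjusted p = 0.919), and the middle probe set of 18S ribosomal RNA by 0.11 (SE 0.15, limma adjusted p = 0.878). The 5' probe sets of 18S RNA, pyruvate carboxylase and Gapdh differed by 0.25, -0.13 and -0.07. Those of pyruvate carboxylase and Gapdh, and the middle one of Gapdh, were also lower in 3 of 3 pairs. The control AFFX-MUR_B2_AT was higher in 3 of 3 pairs. Of the 64 control probe sets, 3 passed with the block, all for the transferrin receptor, and none of the spiked controls did, while 12 of the 64 had an unadjusted limma p under 0.05. Without the block 0 of the 64 passed, and 2 had an unadjusted p under 0.05.

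**Figure D3:**
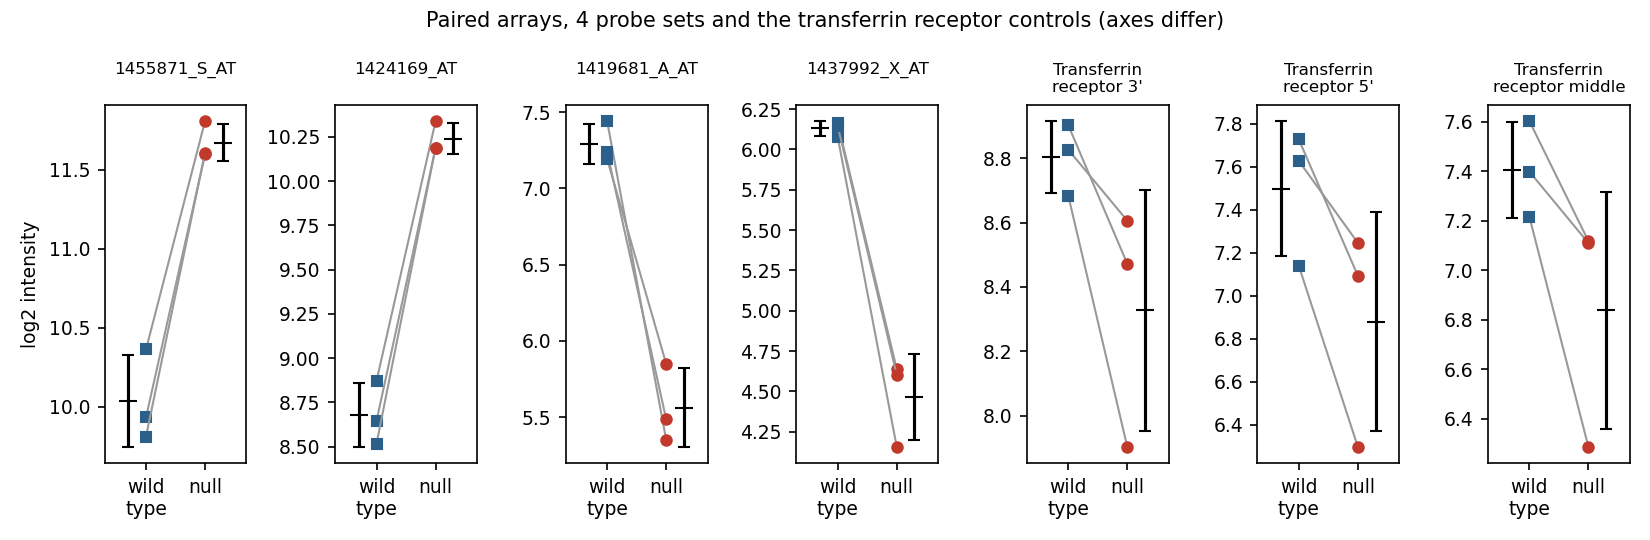
Log2 intensity in wild-type (squares) and null (circles) arrays, with grey lines joining arrays of one replicate number and bars giving the mean ± SD of 3 arrays, for the 2 largest rises and 2 largest falls of the unpaired fit and the 3 transferrin receptor control probe sets. Vertical axes differ between panels and do not start at 0; each line runs the same way within a panel.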

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

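The 51 calls of the unpaired fit stayed between 38 and 60 under no filter, the stricter filter, quantile normalization, median centring and a variance model without intensity trend, and rises made up 74.5%, 75.0% and 75.5% of calls as deposited, after quantile normalization and after centring. At an adjusted p under 0.01, 2 probe sets passed. Leaving out 1 array gave 0 to 58 calls. It gave 0 without null 2 or wild-type 2, where limma still gave 2064 and 1753 probe sets at an unadjusted p under 0.05. The cause was not tested. The replicate block gave 2703. Fits chosen after seeing the data gave 289 calls with the level of spiked poly-A controls as a covariate, 610 with the actin 3'/5' ratio as a covariate, 1072 when both replicate 1 arrays were left out and 2417 with a block that set replicate 1 against the others. The blocked count was 2455 with no filter, 3052 with the stricter filter, 2562 after quantile normalization and 2546 after centring. It was 625 at an adjusted p under 0.01, 191 without the intensity trend and 51 without the block, and leaving out 1 pair gave 606 (without replicate 2), 2045 (without replicate 1) and 2319 calls (without replicate 3). The 4 probe sets given by identifier kept their direction in every setting run. The block changed no call of theirs, and it did change those of the 3 transferrin receptor probe sets. These 3 kept their direction when any array or pair was left out. Without null 3 the unpaired differences shrank from -0.48, -0.57 and -0.62 to -0.27, -0.29 and -0.33 log2 units. Alternatives with a pseudocount do not apply to values that already are logarithms, and those for genes, gene lists and seed sites were not run because probe sets were not paired with genes. Probe set 1437992_X_AT lies below the stricter filter and has no value there. Of the 9008 dimmest kept probe sets 2.03% passed with the block. Without it 11 passed among the dimmest, 8 among those of middle signal and 32 among the brightest. Whether signal over background limits these counts was not tested.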

Other observations

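The replicate block, the filter at the 60th percentile, quantile normalization and median centring were chosen before the values were seen. Their use as tests of an explanation, and the tests with covariates, on RNA degradation, on calls outside the unpaired fit and on a block for replicate 1, were chosen after the first counts had been seen.

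Among the calls of the unpaired fit, 38 rose and 13 fell in miR-223 null cells, an excess of rises that was not present in the blocked fit as a whole (1339 and 1364) but was in its stricter forms, with 64.5% of 625 calls at an adjusted p under 0.01 and 73.3% of 191 calls without the intensity trend. Rises formed 83.3% of unpaired calls at or above the 60th percentile of signal, so the excess was present among brighter probe sets. Whether falls are hidden among dim ones was not decided, because this filter discards dim probe sets. It took falls from 13 to 7 and rises from 38 to 35. With the block at the same filter, 1471 rose and 1581 fell. Quantile normalization left rises at 75.0% of the unpaired calls, and it gained or lost 251 blocked calls. The arrays already lay on one scale, with medians within 0.015 of each other. The test therefore argues only against scale differences left in the deposited values. A shift between genotypes that earlier normalization removed cannot be tested here. A hypothesis is that loss of a repressor of mRNA levels shows first among the larger changes. Among blocked calls that were not calls of the unpaired fit, 52.2% of the 46 of 1 log2 unit or more rose, against 45.8% of the 2011 under 0.5 (two-sided Fisher's exact test p = 0.455), while 59.8% of the 595 of 0.5 to 1 and 63.6% of the 574 at an adjusted p under 0.01 rose, so the hypothesis stays open, and whether the rising probe sets carry miR-223 sites was not tested.

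The replicate 1 arrays deviated together and stood apart in both genotypes, while the correlations did not settle how replicates 2 and 3 pair. Without replicate 1, blocking replicates 2 and 3 still raised the count from 1072 to 2045. The swapped pairing was not run for comparison. Spiked poly-A controls averaged 8.92 on null 1 and 8.77 on wild-type 1, against 8.16 to 8.58 on the other 4 arrays, and spiked hybridisation controls averaged 9.99 and 9.89 against 9.69 to 9.79. The probe set for the B1 repeat, a mobile element present in many mouse transcripts, read 11.33 and 11.17 against 10.38 to 10.65. With the poly-A control level as a covariate in place of the block, 289 probe sets passed, and with the actin 3'/5' ratio 610, of which 286 and 607 were among the 2703 blocked calls. Both counts lay between 270.3, below which the covariate was to be ruled out as the cause, and 1351.5, from which it was to account for the structure. Both covariates set replicate 1 apart, while the 3' minus 5' difference of Gapdh ran the other way (-0.113 and -0.090 against -0.064 to 0.067), so differences in RNA input or labelling and in RNA integrity cannot be told apart from a shared culture or day, which the labels do not record. No biological explanation was tested.

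For the lower transferrin receptor level in null cells, RNA degradation stays open. The receptor's own 3' probe set differed by -0.48 log2 units and its 5' probe set by -0.62. Its 5' minus 3' difference moved by -0.14, so a loss confined to the 5' end covers only part of the fall. The 5' minus 3' difference of actin and Gapdh moved by -0.039 log2 units between genotypes, but both lie near the array maximum. That of the dimmer pyruvate carboxylase and 18S RNA moved by -0.18 and 0.18. The 18S value rests on the replicate 1 pair, with 0.60 there against -0.03 and -0.02 in the pairs of replicates 2 and 3. The mean receptor difference was -0.546 log2 units after quantile normalization and -0.555 before. As the arrays already lay on one scale, this argues only against scale differences left in the deposited values. A change in the cell types of the culture, whose markers were not analysed here, and a change in the neutrophils themselves also stay open. As the transcript was picked after its values were seen and passed only in the blocked fit with an intensity trend, this is a hypothesis.

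Of the 10 ways to split the 6 arrays 3 against 3, 1 gave as many as 51 calls, the real one, and the highest of the others was 0. With the block, 1 of the 4 ways to turn the pairs, the real one, gave 2703 and the highest of the others was 0. These splits are too few for a share under 0.05. At an unadjusted p under 0.05 the split that put null 1, null 2 and wild-type 1 against the rest gave 4673 probe sets, more than the 2881 of the real split. The 4 splits that kept the replicate 1 pair together gave 1922 to 4673, and the other 5 gave 257 to 513, which points to replicate 1 standing apart.

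Single arrays rarely stood alone. On null 2, 3 kept probe sets lay at least 2 log2 units below each of the other 5 arrays, with a largest gap of 7.69 log2 units, and 1 did so on wild-type 2, with a gap of 3.35. No array held a probe set that far above the others. The share of blocked calls was 8.82% among probe sets with the plain suffix _AT, 13.6% with _A_AT, 13.9% with _S_AT and 12.9% with _X_AT.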
